A study of Homo sapiens with 8 samples.

How the data were processed

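Total RNA was measured on Affymetrix human exon arrays in HEK293 cells, a human embryonic kidney line, and in a stable derivative of that line labelled shELL, made to deplete the elongation factor ELL. Per the labels, cells of both kinds were left unstimulated or were given 50 ng/mL EGF for 1 h, and each of the 4 groups held 2 biological replicates, so 8 arrays were analysed. The cells were grown in RPMI with serum and RNA was purified on Qiagen columns, per the labels' protocols.

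The deposited values are log2 probe-set values, 1 per array for each of 287329 probe sets, and per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, whose versions are not given in the sources used here. A probe set is a small group of probes on 1 exon or part of an exon. A further deposited file gave the authors' mean log2 value of the 2 arrays of each group, within 5e-05 of the mean of the array values, together with gene symbols, accessions and positions. The genome build of those positions is not given in the sources used here, so they are printed as deposited.

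The deposited log2 values had not been brought to 1 scale between arrays: array medians ran from 1.33 to 2.95 and 75th percentiles from 2.17 to 5.16. The analysis design fixed before the data were examined had taken the values as already normalized. Quantile normalization between arrays was therefore made the main setting. It was chosen from the array distributions before any model was fitted, although the values of a few genes, ELL and EGR1 among them, had been seen by then. The values as deposited are given beside it as the alternative.

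Probe sets with exactly 1 gene symbol (280649, against 35 with several and 6645 with none) were kept when their mean over the 8 arrays reached the 25th percentile of all probe sets. Genes with at least 3 such probe sets were summarised by median polish of at most 10 iterations, which gave 16145 genes from 209106 probe sets. Of those symbols, 14133 were current in the RefSeq table of the GRCh38 assembly, which served for names alone, 1756 matched there as a synonym of 1 gene, and 256 were unmatched and kept as deposited. A gene value is thus a log2 level over the probe sets of a gene and says nothing of single exons.

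Differences were tested with limma 3.58.1 in R 4.3.3, with input read by data.table, version 1.17.8: a model of the 4 group means over all 8 arrays, with 4 residual degrees of freedom, empirical Bayes moderation and Benjamini-Hochberg adjustment within each of 7 comparisons at 0.05. The comparisons were EGF in control, EGF in shELL, EGF averaged over the lines, shELL against control without EGF, with EGF and averaged over both states, and the interaction, which is the EGF change in shELL minus that in control. Two-sided p-values are given throughout. The number of arrays, 2 per group, limits the precision of every value.

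Across the 23 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 was the main test, with an estimated correlation beside it, and fry as a test of movement in 1 direction. Members were also adjusted over the list alone. The exact permutation test of 4 arrays against 4 has 35 splits and cannot give a p below 0.0286.

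Genes were named by a rule fixed before the data were examined. In each comparison it took up to 15 risers and 15 fallers with adjusted p under 0.05 and no overlap between arrays, or, where fewer than 5 passed, the 5 genes of smallest p, plus ELL, passing members of the immediate-early, MAPK feedback and ELL lists, and up to 4 members of each other list. Passing was read over the list alone for list members, a reading made after values were seen.

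The procedure was tested on simulated data built for EGF in control on 16145 genes. Of 50 genes changed by each fold size, 0% were called at 2-fold, 24% at 4-fold, 84% at 8-fold and 100% at 16-fold, with 6 false calls. A simulated list of 30 genes shifted 1.5-fold gave a camera p of 5.27e-12. Array deviations were drawn independently for each gene, and all changed genes entered the same fit. The shares called therefore do not carry over to these data, where CTGF, 10.3-fold higher with EGF in control, was not called in the main fit. The list value likewise says nothing of lists whose genes move together.

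Alternatives covered the normalization, the probe-set filter, the gene summary, the variance model, array weights, the arrays in the fit, a block on the replicate number and each array left out in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Background was judged from 1225 probe sets of olfactory receptor genes, and for gene values from the 95th percentile of 42 olfactory receptor genes, 2.62, a level chosen after values were seen. Among list members, folds are given where both levels compared lie above it, and log2 differences otherwise.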

Results

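The 8 arrays compared control HEK293 cells with cells labelled shELL, unstimulated or after 1 h with EGF at 50 ng/mL, with 2 biological replicates in each of the 4 groups. Across 16145 genes, replicate arrays correlated at r = 0.954 in unstimulated control, 0.926 in control with EGF, 0.911 in unstimulated shELL and 0.784 in shELL with EGF. Replicate 1 of shELL with EGF was the dimmest array, with a deposited 75th percentile of 2.17 and a median correlation of 0.814 with the other arrays. Most other arrays lay between 0.939 and 0.949, with replicate 2 of control EGF at 0.905 and replicate 1 of unstimulated shELL at 0.910. GAPDH, a glycolytic enzyme, was at 8.03 to 9.10 after normalization in both unstimulated control arrays and replicate 2 of both shELL groups, and at 6.61 to 7.48 in both control EGF arrays and replicate 1 of both shELL groups. This division of the arrays coincides with EGF in control, while each of its sides holds 1 shELL array with EGF and 1 without.

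**Figure D1:**
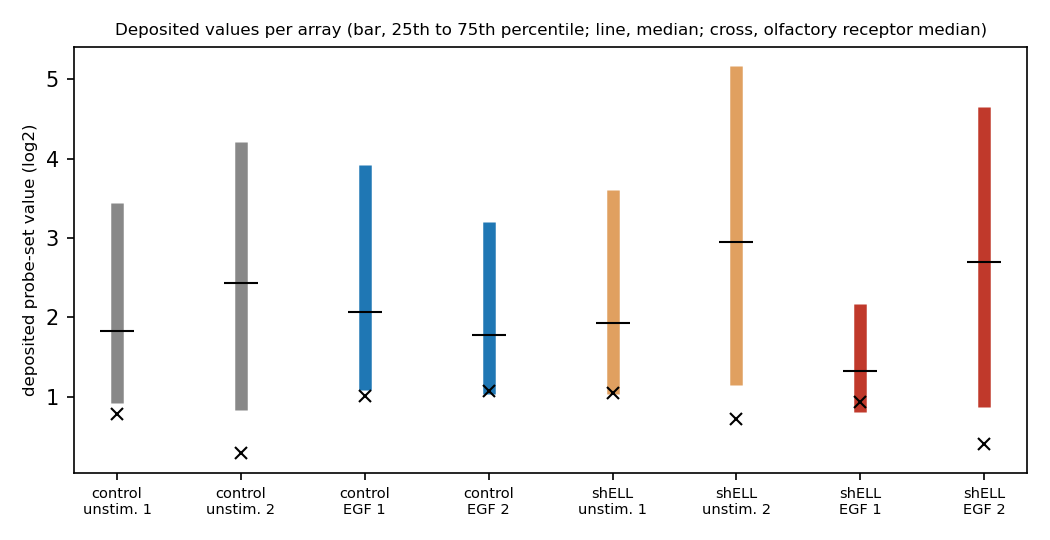
Deposited log2 probe-set values for each of the 8 arrays, with the 25th to 75th percentile as a bar, the median as a line and the median of olfactory receptor probe sets as a cross. The medians run from 1.33 in replicate 1 of shELL EGF to 2.95 in replicate 2 of unstimulated shELL.

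The targeted gene was read first, since it checks the labels. ELL (chromosome 19, 18553568 to 18632917), a factor that raises the rate of RNA polymerase II elongation, was at 2.62 ± 0.18 (log2, SD, n = 4) in the control arrays and 3.02 ± 0.58 (SD, n = 4) in the arrays labelled shELL. The shELL arrays were 0.40 higher on the log2 scale, with a 95% interval from -0.25 to 1.05 and an exact permutation p of 0.171, so the gene value was not lower there. Of its 20 probe sets, 10 were higher and 10 lower in shELL, and 7 lay above the 95th percentile of olfactory receptor probe sets in the control arrays. The gene value in control was close to 2.62, the 95th percentile of 42 olfactory receptor genes, called background below. Of those 7, 5 were lower and 2 higher in shELL (mean -0.28, or -0.60 without replicate 1 of shELL with EGF), while of 8 above that percentile over all 8 arrays, 4 were lower and 4 higher (mean 0.017, or -0.19 without that array). Without replicate 1 of shELL with EGF the difference of the gene value was 0.09. Because the gene value neither shows nor excludes the depletion named in the labels, the groups are called arrays labelled shELL, and every direction between the lines rests on the labels alone.

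Relatives of ELL were read beside it. ELL2 was at 3.47 ± 0.27 (SD, n = 2) in unstimulated control and 3.32 ± 0.38 (SD, n = 2) in unstimulated shELL. EAF1, a partner of ELL, was at 4.68 ± 0.30 and 4.90 ± 0.33 in the same groups. None of the 14 measured members of the ELL, EAF and super elongation complex list passed in any comparison, and the list mean of shELL minus control was -0.07 (camera adjusted p = 0.565).

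EGF in control cells addressed the response to growth factor at 1 h. EGR1 (chromosome 5, 137801491 to 137804949), an immediate-early transcription factor, rose 13.2-fold, from 3.90 ± 0.14 to 7.63 ± 0.09 (log2, SD, n = 2 each), a log2 change of 3.73 with SE 0.33 and a limma adjusted p of 0.0208. An unadjusted p under 0.05 was found for 434 genes where chance gives 807, in a fit that shares the spread over all 4 groups. The number was 1395 with only the arrays of the groups compared, 1252 with array weights and 21 on the values as deposited. It therefore does not measure the EGF response in control. EGR1 was the 1 gene called of 16145. The call ended in 9 of 20 other settings, among them the values as deposited and the leaving out of any 1 of the 6 arrays outside shELL with EGF. The genes of smallest p beside EGR1 were CTGF (3.36 higher, adjusted p = 0.176), NR4A2 (1.93), EGR2 (2.29) and IER2 (2.33), none of which passed over all genes. CTGF, a secreted matricellular protein now named CCN2, was at 3.92 ± 0.80 unstimulated and 7.28 ± 0.38 with EGF (SD, n = 2 each).

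Immediate-early transcription factors rose as a group in control cells with EGF, by 0.92 on average over 29 measured genes (camera adjusted p = 2.33e-15, and 0.0488 with an estimated correlation). Adjusted over the list alone, 11 rose and 0 fell, against 1 adjusted over all genes. They were EGR1, EGR2, EGR3, FOS, FOSB, JUN, ATF3, IER2, MYC, NR4A1 and NR4A2. FOS, a subunit of AP-1, went from 1.76 ± 0.52 to 3.80 ± 0.37 and IER2 from 2.59 ± 0.69 to 4.92 ± 0.18 (SD, n = 2 each). Genes of MAPK feedback and mRNA decay averaged 0.56 higher over 26 genes (camera adjusted p = 2.31e-06, and adjusted p = 0.0562 with an estimated correlation), and 4 rose over the list alone. These were DUSP1, a phosphatase of MAP kinases, SPRY4, a Sprouty inhibitor of receptor signalling, ERRFI1, an inhibitor of the EGF receptor, and GADD45B.

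SRF and YAP target genes, many of them cytoskeletal, averaged 0.52 higher over 19 genes in control cells with EGF (camera adjusted p = 0.00183, and adjusted p = 0.610 with an estimated correlation). CTGF and CYR61, now named CCN1, rose over the list alone, the latter 5.24-fold. PTGS2, the inducible cyclooxygenase, rose by 2.16 in log2 value, from a level of 2.34 that is not above background, over the NF-kB and cytokine list alone, whose camera adjusted p was 0.269. Lower list means were found for mitosis genes (-0.23, camera adjusted p = 0.00234) and DNA replication genes (-0.17, 0.0203), with adjusted p = 0.676 for both with an estimated correlation. The mitosis call ended without replicate 2 of control with EGF (-0.073), and the DNA replication call without that array (-0.051) or replicate 2 of unstimulated control (-0.098), while without replicate 1 of control with EGF the means were -0.39 and -0.29. Mitosis genes followed the division of the arrays seen for GAPDH, at 4.44 to 4.51 on the side of unstimulated control and 3.69 to 4.40 on the other, and in shELL the EGF difference was 0.045 and -0.52 on the respective sides. Fibroblast markers, a list of another cell type, averaged 0.37 higher in the same comparison (camera adjusted p = 0.0420, and adjusted p = 0.676 with an estimated correlation), a call that ended without replicate 2 of unstimulated control (0.20) or either replicate of control with EGF (0.41 and 0.33). Their list means followed the GAPDH division too, at 1.46 to 1.81 and 1.96 to 2.45, all below background.

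**Figure D2:**
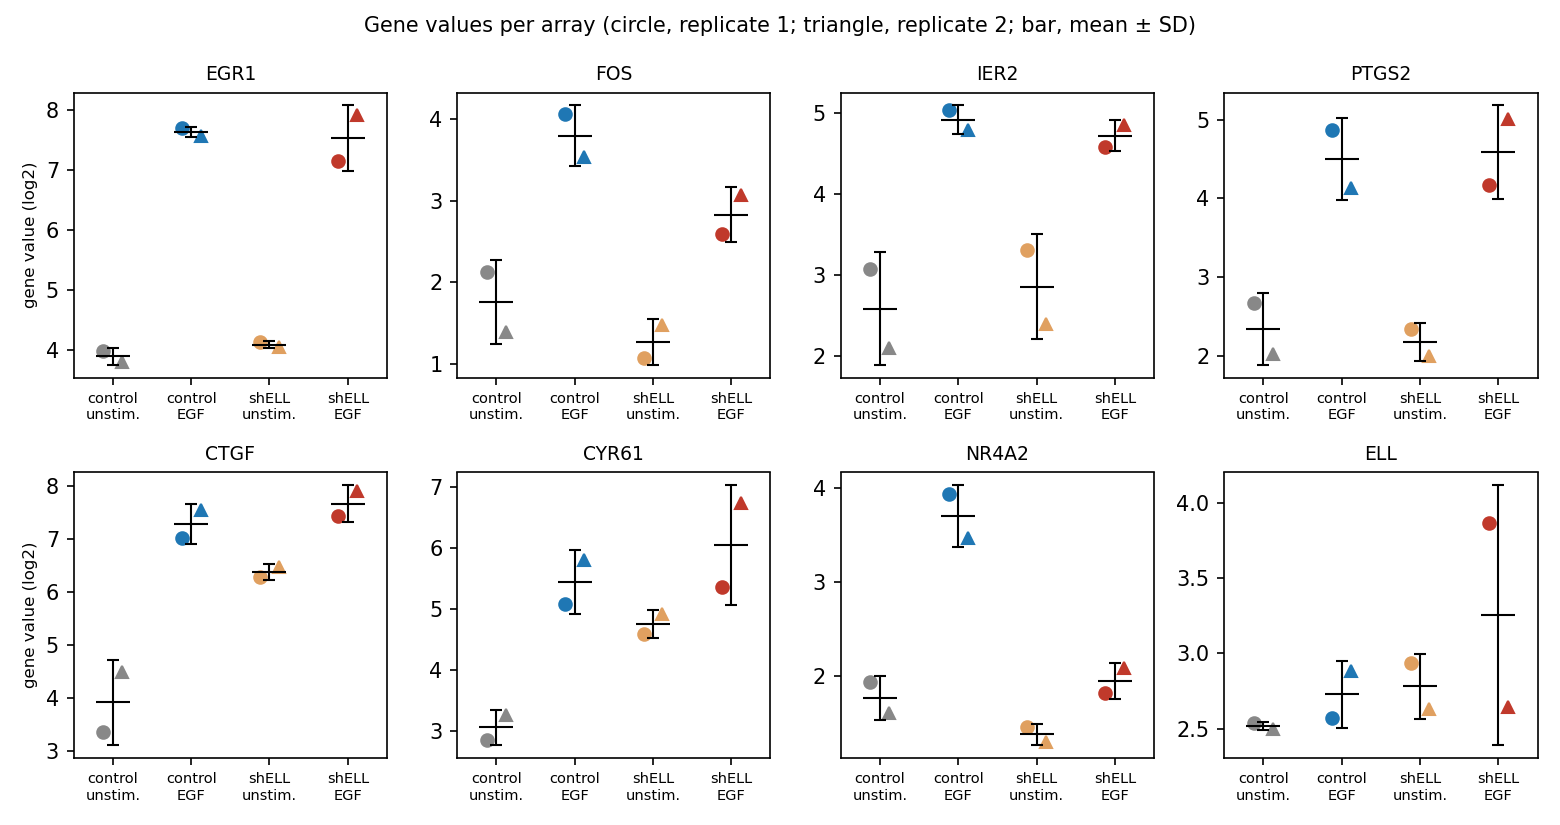
Log2 gene values of 8 genes in the 4 groups, with circles for replicate 1, triangles for replicate 2 and bars for mean ± SD. EGR1 lies near 4 in the unstimulated arrays (group means 3.90 and 4.10) and at 7.63 and 7.53 with EGF, while ELL is highest in replicate 1 of shELL EGF.

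EGF in the arrays labelled shELL gave the corresponding comparison in the other line. EGR1 rose 10.8-fold, from 4.10 ± 0.06 to 7.53 ± 0.54 (SD, n = 2 each), a log2 change of 3.43 with SE 0.33 and a limma adjusted p of 0.0417. It was again the 1 gene called, with 398 at an unadjusted p under 0.05. PTGS2 rose over its list alone, by 2.42 in log2 value from 2.17, which is not above background. GPR50, an orphan receptor of the melatonin receptor family, was 1.85 higher and SSSCA1, now ZNRD2, -1.59 in log2 value, and neither passed. The call of EGR1 ended in 16 of 20 other settings, among them the values as deposited and the leaving out of any array other than replicate 1 of shELL with EGF.

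The immediate-early list averaged 0.67 higher in shELL with EGF (camera adjusted p = 1.57e-11, and 0.0418 with an estimated correlation), while on the values as deposited its mean was -0.06 and the median of all genes -0.68. FOS, EGR1, ATF3 and IER2 rose over the list alone, FOS from 1.27 ± 0.28 to 2.83 ± 0.34 (SD, n = 2 each). MAPK feedback and mRNA decay genes averaged 0.54 higher (camera adjusted p = 6.79e-10, and 0.0418 with an estimated correlation), and -0.24 on the values as deposited. None of its 26 members passed over the list alone. Neither list followed the GAPDH division: on its sides the EGF difference in shELL was 0.76 and 0.57 for immediate-early factors, 0.63 and 0.45 for MAPK feedback genes, and 3.859 and 3.001 for EGR1. The SRF and YAP list averaged 0.16 (camera adjusted p = 0.354), and fibroblast markers 0.25 (camera adjusted p = 0.0832).

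Averaged over both lines, EGR1 was 11.9-fold higher with EGF (log2 change 3.58, SE 0.23, limma adjusted p = 0.00152), in 4 of 4 arrays. No other gene passed, and 511 had an unadjusted p under 0.05. Over the list alone, 14 of 29 immediate-early factors rose, now with KLF4, KLF10 and NR4A3. In the MAPK feedback list, 9 of 26 rose: ZFP36, an mRNA decay factor, by 3.01-fold, MCL1, a survival factor, by 1.89-fold, DUSP1, DUSP5, SPRY4, ERRFI1, GADD45B, PPP1R15A and BTG2. CTGF, CYR61 and THBS1 rose over the SRF and YAP list alone and PTGS2 over the cytokine list alone. The means of the immediate-early and MAPK feedback lists were each higher in all 4 EGF arrays. Each had an exact permutation p of 0.0286, the smallest this design allows, and 0.329 after adjustment over 46 such tests. The call of EGR1 ended in 2 of 19 other settings, the values as deposited and array median centring, where no gene passed.

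**Figure D3:**
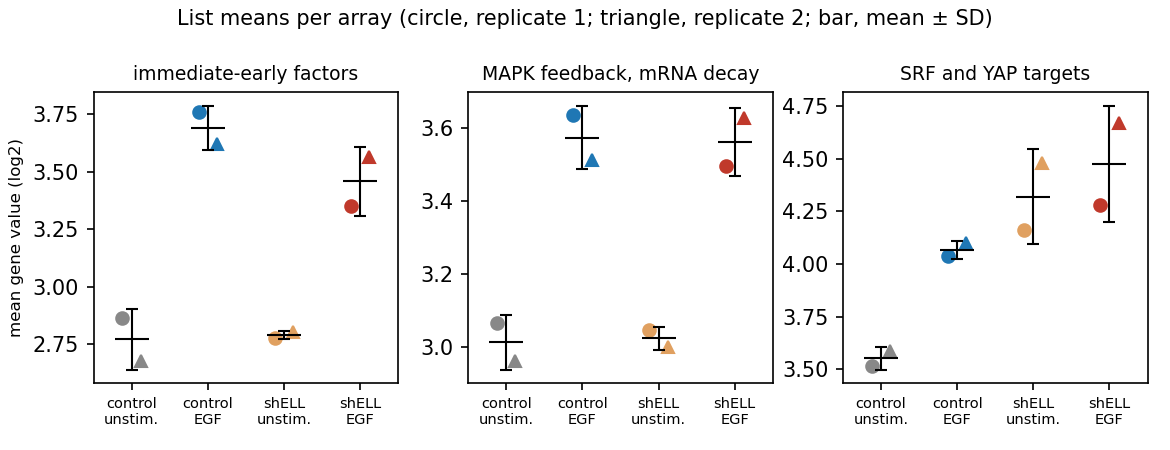
Mean log2 gene value of 3 lists in each array, with circles for replicate 1, triangles for replicate 2 and bars for mean ± SD. The immediate-early list averages 0.92 higher with EGF in control and 0.67 higher in shELL, and the SRF and YAP list is lowest in unstimulated control.

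Unstimulated shELL was compared with unstimulated control for the difference between the lines at rest. SRF and YAP target genes were higher as a group, by 0.77 on average over 19 genes (camera adjusted p = 3.07e-14, and adjusted p = 0.162 with an estimated correlation). Over the list alone, 4 genes were higher: CTGF by 5.49-fold, CYR61 by 3.25-fold, ANKRD1, a muscle ankyrin repeat protein, by 2.15 in log2 value, and THBS1, thrombospondin, by 1.12. ANKRD1 and THBS1 were not above background in control (2.34 and 1.61). No gene passed over all genes with limma, and 206 had an unadjusted p under 0.05. The list call was kept with every array left out, with means above 0.

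KRT17, a keratin of basal epithelia, was at 2.42 ± 0.11 in control and 4.46 ± 0.17 in shELL (SD, n = 2 each) and was higher over the list of keratinizing epithelium markers alone. That list, of another cell type, averaged 0.44 higher (camera adjusted p = 0.00571, and adjusted p = 0.369 with an estimated correlation), a call that ended without replicate 1 of unstimulated control (0.40) or replicate 2 of unstimulated shELL (0.41). GLIPR1 was 2.53 higher in log2 value and IRS4, an insulin receptor substrate, -1.71, and neither passed. SLC2A3, a glucose transporter, fell 2.35-fold over the hypoxia and glycolysis list alone. Means of -0.23 were found for cholesterol synthesis, heat shock and ribosomal protein genes alike, with camera adjusted p of 0.0192, 0.0192 and 0.00479 and an adjusted p of 0.749 for each with an estimated correlation. Each call ended with 1 array left out: cholesterol synthesis without replicate 1 of unstimulated control (0.082) or of unstimulated shELL (-0.21), heat shock without replicate 1 of unstimulated shELL (-0.12) or replicate 2 of unstimulated control (-0.13), and ribosomal proteins without the same arrays (-0.020 and -0.16). The means for cholesterol synthesis without replicate 2 of unstimulated control (-0.55) and for ribosomal proteins without replicate 2 of unstimulated shELL (-0.44) were larger in size.

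**Figure D4:**
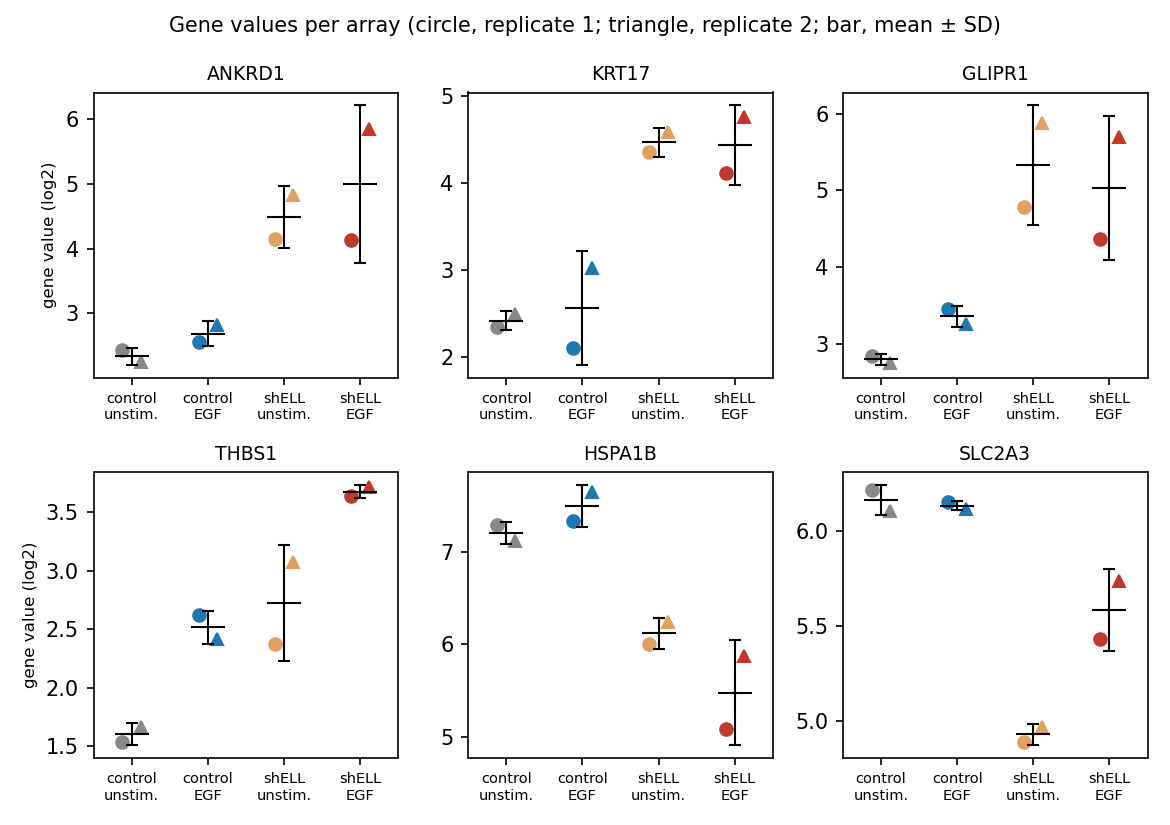
Log2 gene values of 6 genes in the 4 groups, with circles for replicate 1, triangles for replicate 2 and bars for mean ± SD. KRT17 and ANKRD1 lie above all control arrays in each array labelled shELL, and HSPA1B lies at 6.12 and 5.48 in the shELL groups against 7.20 and 7.49 in the control groups.

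The lines were also compared with EGF present. No gene passed over all genes with limma, and 511 had an unadjusted p under 0.05. ANKRD1 was higher over the SRF and YAP list alone, at 2.69 ± 0.19 in control and 4.99 ± 1.22 in shELL (SD, n = 2 each). The list averaged 0.41 higher (camera adjusted p = 0.000302, and adjusted p = 0.791 with an estimated correlation), and 0.21 without replicate 2 of shELL with EGF, where the call was lost. NR4A2, an orphan nuclear receptor, was lower in shELL over the immediate-early list alone, at 3.70 ± 0.33 in control and 1.95 ± 0.19 in shELL (SD, n = 2 each), the latter not above background. KRT17 was again higher over its list alone, by 1.87 in log2 value. HSPA1B, an inducible HSP70 whose sequence is nearly that of HSPA1A, so that its level is uncertain, was 4.03-fold lower over the heat shock list alone. Cholesterol synthesis genes averaged -0.46 (camera adjusted p = 0.00855, and adjusted p = 0.969 with an estimated correlation). Without replicate 1 of control with EGF this mean was 0.021 and without replicate 1 of shELL with EGF -0.34, neither of them called, and without replicate 2 of control with EGF it was -0.94.

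Averaged over both EGF states, shELL arrays had higher SRF and YAP targets, by 0.59 over 19 genes (camera adjusted p = 5.98e-13, and adjusted p = 0.192 with an estimated correlation). Over the list alone, 8 were higher: ANKRD1, by 2.23 in log2 value, CTGF, THBS1, CYR61, CNN2, TPM1, TPM4 and CALD1, the last 4 being actin-binding proteins. Markers of keratinizing epithelium averaged 0.36 higher in the same arrays (camera adjusted p = 0.00479, and adjusted p = 0.321 with an estimated correlation), or 0.27 and not called without replicate 1 of control with EGF. The median of these 11 markers was 0.21, 5 of them lay above background in an unstimulated group, and KRT17 was the only member that passed over the list alone. KRT17 was higher by 1.96 in log2 value, in 4 of 4 shELL arrays, and HSPA1B 2.92-fold, CCNG1 2.21-fold and SLC2A3 1.86-fold lower, each over its list alone. NR4A2 was lower by 1.07 in log2 value over the immediate-early list alone (log2 change -1.07), with its shELL level of 1.66 not above background. The exact permutation p of the SRF and YAP list mean and of the keratinizing epithelium list mean was 0.0286, and 0.329 after adjustment. No gene passed over all genes with limma, 426 had an unadjusted p under 0.05, and without replicate 1 of shELL with EGF 1 gene, ANKRD1, was called.

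The interaction asked whether the EGF change differed between the lines. EGR1, the 1 gene of the EGF-responsive set, had an interaction of -0.30 in log2 value, with SE 0.46, which did not pass. For this EGF-responsive gene set in the interaction the value was -0.68 without replicate 2 of shELL with EGF and 0.088 without replicate 1. Its size and direction therefore depend on 1 array. Immediate-early factors averaged -0.25 (95% interval -0.69 to 0.18), MAPK feedback genes -0.02 (-0.32 to 0.28) and SRF and YAP targets -0.36 (-1.07 to 0.35). CTGF had an interaction of -2.07 (SE 0.59) and SMAGP, a small membrane protein, 2.15 (SE 0.40), and neither passed. No gene was called with limma, 280 had an unadjusted p under 0.05, and 0 of 23 lists passed.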

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

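Array median centring, the 5 arrays of highest agreement, the crossed replicate block and the 50 risers were chosen after seeing the data. Of the alternative values of the counts, the lead lists, the ELL level and the EGF-responsive set, 330 kept their direction and side of the threshold or lay within 1.5 times the count, 40 counts moved, 6 values were weaker, 4 stronger and 3 reversed. For single genes 641 stayed, mostly uncalled, 13 were stronger and 27, all of EGR1, lost their call. The cause was not tested except where fewer arrays or genes entered the fit. The signal over background limits dim genes: the 75th percentile lay 1.23 above the olfactory receptor median in replicate 1 of shELL with EGF and 4.44 in replicate 2 of unstimulated shELL. The other value table holds group means alone, so that setting was not run.

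On the values as deposited 0 genes were called for EGF in control, EGF in shELL and EGF averaged over the lines, and the means of the immediate-early and MAPK feedback lists in shELL with EGF turned to -0.056 and -0.24, with the median of all genes at -0.68. That median lay at 0.49 for unstimulated shELL and -0.66 for the interaction. Array median centring likewise called 0 genes in those 3 comparisons. With the estimated inter-gene correlation the gene lists called fell from 42 to 5 of 161 pairs of list and comparison. The means of MAPK feedback genes in control with EGF (0.56) and of SRF and YAP targets in control with EGF (0.52), unstimulated shELL (0.77), shELL with EGF (0.41) and shELL averaged (0.59) were then not called.

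With the replicate block 2 genes were called for EGF in control, 0 for EGF in shELL and 2 for EGF averaged. The EGF-responsive gene set in the interaction, then 2 genes, was -1.18 and passed with fry. The replicate differences of control with EGF correlated at -0.16, -0.24 and -0.31 with those of the other groups, and those of the other pairs of groups at 0.37 to 0.51, so the numbers were not taken to pair the samples. A block with the control EGF numbers crossed called 1 gene in each of the 3 EGF comparisons.

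EGF in shELL called 0 genes with the 50th percentile filter, the plain mean over probe sets, at least 1 probe set per gene, the intensity trend and robust prior, array weights, and the arrays of the groups compared. At least 1 probe set per gene called 0 for EGF in control, array weights called 2 there, and the plain mean called 2 for EGF averaged and gave an immediate-early interaction of -0.29, which passed. With the 5 arrays of highest agreement, 12 genes were called for EGF averaged, 1 for unstimulated shELL, 1 for shELL with EGF, 3 for shELL averaged, and 24 pairs of list and comparison, but 3 of the 4 groups then hold 1 array, with 1 residual degree of freedom.

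Leaving out each array in turn gave 0 to 1 genes each for EGF in control, EGF in shELL and shELL averaged. A lone array was assumed to vary like the other groups. Of the 42 called pairs of list and comparison, 9 kept their call and direction with every array left out, all of them of the immediate-early, MAPK feedback and SRF and YAP lists, and 33 did not. The number of gene lists called ranged from 25 to 65, the ends being without replicate 2 of unstimulated control and of shELL with EGF. The SRF and YAP mean in shELL with EGF ranged from 0.21 to 0.60. The EGF-responsive gene set in the interaction ranged from -0.68 without replicate 2 of shELL with EGF to 0.088 without replicate 1. The 50 risers of smallest p for EGF averaged had a mean interaction of -0.37, 39 of 50 lower in shELL, which passed with fry. Without replicate 2 of shELL with EGF the same 50 had -0.37 and risers picked anew 0.79.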

Other observations

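The tests on the SRF and YAP list, those against other cell types among them, on the single ELL probe set, on the immediate-early rise, on 3' probe sets, on lists along the split of 246 genes, and on the dim array and exchanged labels for ELL were chosen only after the result was seen.

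Targets of p53 averaged -0.18 in shELL minus control at rest (camera adjusted p = 0.0192, and adjusted p = 0.517 with an estimated correlation) and -0.19 over both EGF states (0.0151, and adjusted p = 0.526 with an estimated correlation). The call at rest ended without replicate 1 of unstimulated control (-0.13) or of unstimulated shELL (-0.086), and the mean was -0.27 without replicate 2 of unstimulated shELL. The averaged call ended without replicate 1 of control with EGF (-0.18), of unstimulated shELL (-0.15) or of shELL with EGF (-0.14). Elongation and pausing factors other than the ELL complexes averaged -0.15 with EGF in control (camera adjusted p = 0.0256, and adjusted p = 0.676 with an estimated correlation). That call ended without replicate 2 of unstimulated control (-0.041) or of control with EGF (-0.088), and the mean was -0.25 without replicate 1 of unstimulated control.

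Interferon response genes averaged 0.31 higher with EGF in control, 22 of 27 being higher (camera adjusted p = 0.0445, and adjusted p = 0.676 with an estimated correlation), and the call ended without either replicate of unstimulated control (0.39 and 0.23) or replicate 2 of control with EGF (0.20). Their means followed the GAPDH division of the arrays whatever the EGF state or line, at 1.94 to 2.10 on the side of unstimulated control and 2.22 to 2.66 on the other, below the background of 2.62 in all arrays but 1, and the EGF difference in shELL was -0.0074 and 0.31 on the respective sides. Nuclear genes of the respiratory chain averaged -0.26 with EGF in shELL (camera adjusted p = 0.0349, and adjusted p = 0.855 with an estimated correlation), against 0.0074 without replicate 1 of shELL with EGF and -0.24 without replicate 2 of unstimulated shELL, neither called, and -0.53 without replicate 2 of shELL with EGF. Genes of the EGF receptor family and its ligands averaged 0.18 higher in shELL over both EGF states (camera adjusted p = 0.0193, and adjusted p = 0.321 with an estimated correlation), and the call ended without replicate 1 of control with EGF (0.18), of unstimulated shELL (0.11) or of shELL with EGF (0.13), or replicate 2 of shELL with EGF (0.23).

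ELL probe set 3855013 (chromosome 19, 18553706 to 18553793), next to the 3' end of the ELL probe sets on the minus strand, was at 0.27 ± 0.60 in the control arrays and 3.47 ± 0.48 in the arrays labelled shELL (log2, SD, n = 4 each), the control level being far below 2.92, the olfactory receptor 95th percentile, with no overlap and an exact permutation p of 0.0286, the smallest possible. It ranked 10 of 287329 probe sets by p, although it did not pass over all of them (limma adjusted p = 1.00), and the probability that 1 or more of 20 ELL probe sets ranks so high by chance is 0.000696. The 4 nearest ELL probe sets differed by 0.13 on average, between -0.62 and 0.65, but in the control arrays 0 of the 4 lay above that percentile. In the shELL arrays 3855014 (3.31, a difference of 0.50) and 3855015 (3.02, 0.65) lay above it, and 3855012 (1.39) and 3855016 (1.98) did not. A higher level of the 3' part of ELL mRNA therefore stays open. The difference of probe set 3855013 was 2.86 in the 5 arrays of highest agreement, where 3 of the 4 groups hold 1 array (1 residual degree of freedom), so low signal stays open. Another hypothesis left open is that this probe set may read RNA from the hairpin construct, which needs the sequence of the construct and was not tested.

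The ELL gene value was not lower in the arrays labelled shELL, and without replicate 1 of shELL with EGF the difference was 0.091 (SE 0.21). The 7 of 20 probe sets above the olfactory receptor level in control then averaged -0.60 (SE 0.20 over probe sets), a choice that favours lower values in shELL, and the 8 above it over all 8 arrays -0.19 (SE 0.26). So a fall hidden by 1 dim array, or by a signal too close to background, cannot be told apart from an unchanged ELL mRNA. An exchange of labels between 1 control and 1 shELL array also stays open. As labelled, 418 genes separated the lines (2.59% of genes, where chance gives 2.86%), and at most 1073 did in the 16 such exchanges. The largest gap, however, was 1.30 as labelled and 0.86 in the exchanges. Some exchanges also bring the grouping nearer to the division of the arrays seen for GAPDH. A higher count of separated genes therefore does not by itself point to exchanged labels. A depletion of ELL protein without loss of mRNA was not measured.

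Higher SRF and YAP targets in shELL could be chance, array quality, other cells or a property of the line. Only 1 of the 35 splits, the labelled one, gave a list difference as large, the smallest share 35 splits allow, and by a narrow margin, 0.59 against 0.56 for the highest other split. In the 5 arrays of highest agreement the difference was 0.78 (95% interval 0.16 to 1.41), with 1 array in 3 of the 4 groups and 1 residual degree of freedom, so low signal is not excluded. The fibroblast list differed from the SRF and YAP list by -0.57 at rest (SE 0.19 over genes, not arrays). However, 9 of 11 markers were higher and only COL1A1 lay above background (2.974 in unstimulated control, 3.505 in unstimulated shELL). The keratinizing epithelium list differed from the SRF and YAP list by -0.33 (SE 0.27 over genes, not arrays). Neither cell type is therefore excluded. These cells, and a difference between the stable lines, whether from ELL depletion or from selection of the line, stay open, and the design cannot separate the last pair.

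The immediate-early rise averaged 0.92 in control and 0.67 in shELL, and without replicate 1 of shELL with EGF the gap was 0.15, between the sizes set for and against an effect of that dim array, so the effect of the array and that of the line cannot be told apart.

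For EGF averaged, a fit of 4 arrays against 4 called 3 genes, and 2 of 35 splits called as many, so chance is not excluded for the count. The other split put both unstimulated control arrays and the second replicates of both shELL groups on 1 side and called 246 genes, which points to a structure of the arrays other than the groups. The means of 8 of 23 lists, and GAPDH, separate along it without overlap, against at most 3 lists in any other split. In control this split is the same as EGF against no EGF, so the EGF values there cannot be separated from this structure by themselves, whereas the EGF differences in shELL are balanced over it. EGR1 and the immediate-early and MAPK feedback lists do not separate along it. For shELL averaged the fit called 0 genes, a count that all 35 splits reach, up to 246, so this count cannot test chance.

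A hypothesis that longer genes are lower in shELL, as loss of an elongation factor could give, was tested across 15930 genes, which are not independent replicates. Spearman's rho between genomic span and the shELL difference was -0.00303, and 34 of 35 splits gave a rho as large in size, so no such relation was detected. The 3' minus 5' probe-set difference was -0.016 in shELL minus control (exact permutation p = 0.543).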
